A study of Mus musculus with 4 samples.

How the data were processed

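RNA was measured in cultured neural precursor cells isolated from the cortices of ICR mouse embryos at embryonic day 12. The cells were expanded with basic fibroblast growth factor and epidermal growth factor and exposed for 2 hours to supernatant of a retrovirus carrying the empty vector pCL (Control), Nurr1, Foxa2, or both. The growth factors were then withdrawn for 2 days of differentiation, per the labels' protocols. Nurr1 is the protein made by Nr4a2. Total RNA was taken with Trizol and turned into biotinylated complementary RNA for a single-colour Illumina mouse bead array, again per the labels' protocols. There were 4 arrays, with 1 per group, and each array belongs to the group its title names.

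Per the file headers, the deposited scanner table gives for each of 25697 probes a mean bead signal (intensity on a linear scale, without normalization between arrays) and a detection p-value per array. No value of the signal was negative, and the lowest signals lay between 59.7 and 63.9, so background had not been subtracted. The detection p-value, also deposited by the authors, came in steps that correspond to 798 negative-control bead types on each array. The authors' deposited value table holds log2 values of 13246 of these probes. Each of its columns ranked the probes as the signal of the same array did (Spearman's rho 1.00 after rounding), and all 4 columns had the same distribution, with a median of 9.04. These values are therefore log2 signals with quantile normalization and without centring or background subtraction, a description taken from the values. The scanner software, the software behind the value table and the rule that selected its probes are not given in the sources used here. The value table held all 11780 probes with a detection p-value of at most 0.05 on all 4 arrays and 1466 others.

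Gene symbols came from the platform annotation of the probes in the authors' value table. Of those probes 12484 had 1 symbol, none had several and 762 had none. Entrez identifiers of 12480 probes were found in the RefSeq gene table of mouse assembly GRCm38.p6, and no symbol had to be updated. The 12451 probes outside the value table are unnamed here, and 305 of them were detected on at least 1 array. Genes bright on a single array can be among these unnamed probes. Foxa2 has no named probe here, so its level was not analysed. The named probes represent 8980 genes, of which 2454 had more than 1 probe. Where a gene had several, the probe with the highest mean normalized signal over the 4 arrays stood for it. A fold is that of this probe, and dimmer probes of the same gene can give smaller ones.

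Signals were corrected for background and normalized with limma 3.58.1 in R 4.3.3. The function neqc estimated background from the detection p-values, added an offset of 16, applied quantile normalization over all 4 arrays and took log2. Tables were handled with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and figures drawn with matplotlib 3.10.9. A probe counted as detected on an array at a detection p-value under 0.01. Detected probes numbered 10971 on the Control array, 11316 on the Nurr1 array, 11460 on the Foxa2 array and 11420 on the array with both factors. For a gene not detected on the dimmer array, that value was raised to the lowest normalized signal among probes detected there, and the resulting fold is a bound, written "at least". Where neither array detected a gene, or the bound was under 1-fold, no difference was given and the gene entered list medians as 0. A gene counted as higher or lower when the brighter array detected it and the log2 difference was at least 1, which is 2-fold. Folds come from background-corrected, normalized values, while signals quoted in the text are the deposited ones, so their ratios differ. A fold against a value just above the lowest detected signal counts as measured, but is little firmer than a bound.

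No test between groups was made with 1 array per group, and no p-value is given for any comparison. A model of the separate effects of Nurr1 and Foxa2 would leave 1 residual degree of freedom, but its error would be the joint action in question, and it was not fitted. All counts, folds and list positions describe these 4 arrays, and their number limits the precision. The spread between different probes of the same gene is the only error given. Over genes with at least 2 detected probes, the standard deviation of the log2 difference between probes was 0.18 for Nurr1 against Control, 0.19 for Foxa2 against Control and 0.23 for both factors against Control. It was 0.20 for both factors against either single factor. That spread holds probe effects and array noise and leaves out differences between cultures, transductions and RNA preparations. Signs were compared over probes detected on both arrays, in genes whose mean over these probes differed at least 2-fold. All had the same sign in 85 of 85, 47 of 47, 140 of 140, 79 of 79 and 120 of 120 genes. The order of comparisons is the one just given, with both factors against Nurr1 before both factors against Foxa2. With so small a spread, a mean past 2-fold made a shared sign foreseeable, so these counts add little. Dimmer probes were left out of them.

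The arrays were compared in 3 contrasts with Control, and the array with both factors also with each single-factor array. Joint action was described by the departure from additivity on the log2 scale, which is the value with both factors minus that with Nurr1 minus that with Foxa2 plus that of Control. Departures were counted over the 7127 genes detected on all 4 arrays. For genes and lists with undetected values, these were raised to the highest of the 4 arrays' floors, which can move a departure either way.

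Gene lists, 33 in all, were fixed before the data were examined: dopamine neuron phenotype, midbrain and floor plate development, hedgehog response, liver and endoderm genes associated with FOXA2, neural progenitor and radial glia, cell cycle, cell cycle exit inhibitors, pan-neuronal, neurogenic transcription factors, cortical glutamatergic, GABAergic and ventral forebrain, other monoaminergic and cholinergic, oligodendrocyte lineage, astrocyte, microglia and macrophage, endothelial and pericyte, fibroblast and meninges, choroid plexus and ependyma, neural crest and peripheral neuron, interferon response, inflammatory and NF-kB, apoptosis and p53, oxidative stress defence, neurotrophic factors and receptors, Wnt signalling, Notch signalling, BMP and TGF-beta response, growth factor signalling feedback, nuclear receptor 4A family and partners, cholesterol synthesis, hypoxia and glycolysis, unfolded protein and heat shock response, and housekeeping reference genes. A list's median over members detected on at least 1 array was placed among 10000 random lists of the same size, matched on mean signal in 20 bins. Lists with fewer than 5 measured members were not placed, which left 27 lists and 162 positions. A position below the percentile 2.5 or above 97.5 is called outside the random range. By chance 8.1 of 162 would lie there if the genes within a list varied independently. Genes that vary together between cultures would put more lists outside it. Some genes belong to more than 1 list. The Wnt, Hedgehog, and BMP and TGF-beta lists each hold genes that promote and genes that restrain the pathway. Their medians therefore give no direction of its activity.

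Named genes followed a rule fixed before the data were examined. Nr4a2, Foxa2 and Th were always named. For each contrast with Control it took up to 8 genes with the highest and 8 with the lowest difference among those detected on both arrays, and up to 4 bounds in each direction among those detected on 1. For the array with both factors against each single factor, and for the departure from additivity, it took up to 5 in each direction. Of each list described it took up to 4 members with the greatest absolute difference and any member past 2-fold. Genes without a symbol, and symbols that are only clone or locus identifiers, were counted but not named.

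The whole procedure was tested on simulated arrays made from the Control signals, with noise of 0.14 (SD, log2) per array. For Nurr1 against Control, 200 of 8980 genes were given known changes. These genes, and those raised only with both factors, were drawn from genes well above background on the Control array. Recovery of genes dim or undetected there was not tested. Of 50 genes changed 2-fold 42.0% passed the 2-fold threshold, and all 50 did at each of 3-fold, 4-fold and 8-fold. Of 8498 unchanged genes 6 passed. For the departure from additivity, 100 of 100 genes raised 4-fold only with both factors passed, as did 37 of 8150 unchanged genes. In simulated Foxa2 against Control, where no list was changed, 2 of 28 lists lay outside the random range. The noise was drawn separately for each probe and left out differences between cultures, transductions and RNA preparations. These counts therefore check the procedure and are not error rates for the comparisons reported here.

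Other settings, fixed before the deposited values were opened, numbered 9: no background correction, scaling to equal medians in place of quantile normalization, an offset of 50, detection at a p-value under 0.05, no detection filter or floor, the mean over a gene's probes, the authors' deposited log2 values, additivity on the linear scale, and random lists not matched on signal. The authors' values also lack background correction, so that setting and the first are nearly the same and are not separate checks. Labels and files gave no slide, batch or date, so none was tested.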

Results

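Expression was measured on 4 bead arrays of mouse cortical neural precursor cells, 1 each for the empty retrovirus (Control), Nurr1, Foxa2 and both factors together. RNA was taken after 2 days without growth factors. Nurr1 is a nuclear receptor, and Foxa2 a forkhead transcription factor of the floor plate, and the series asks whether they act together in the induction of dopamine neurons. The median deposited signal was 134 on the Control array, 138 on the Nurr1 array, 145 on the Foxa2 array and 149 on the array with both. Between 42.7% and 44.6% of probes were detected. Of 8980 named genes, 8230 were detected on at least 1 array and 7127 on all 4. Over probes detected on all 4 arrays, the correlation of log2 values across probes, which are not independent replicates, ranged from 0.933 between Control and both factors to 0.972 between Control and Foxa2. There was no replicate of any group, so every difference stands without a replicate check.

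The probe for Nr4a2, the gene of Nurr1, had a signal of 167 on the Control array, 1669 on the Nurr1 array, 216 on the Foxa2 array and 1620 on the array with both factors. The arrays labelled with Nurr1 thus had the higher Nr4a2 values, 17.0-fold and 15.2-fold above Control. The Foxa2 array lay 1.25-fold above Control. The Control signal was just above the lowest detected signal of the Control array (166), so these folds stand close to bounds. Whether the probe lies in the part of the transcript carried by the virus is not known here. The Foxa2 transcript itself was not analysed because no named probe represents it.

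With Nurr1 alone, genes of several kinds were higher than with the empty virus. The glycolytic enzyme gene Eno3 was 78.0-fold higher, Minar2 59.8-fold, the insulin-like growth factor binding protein gene Igfbp3 31.0-fold and the glypican gene Gpc3 23.1-fold. Slc35f3 was 12.5-fold higher, the matricellular growth factor gene Ccn2 12.4-fold and Rasl11b 12.1-fold. Others were not detected on the Control array: the matrix protein gene Spon2 was at least 65.4-fold higher, the pigment enzyme gene Tyrp1 at least 56.2-fold, the lipoprotein lipase gene Lpl at least 36.5-fold and Dgkk at least 25.2-fold. In all 346 genes were at least 2-fold higher and 221 at least 2-fold lower. Th, encoding tyrosine hydroxylase, the rate-limiting enzyme of dopamine synthesis, had a signal of 188 with Nurr1 and was not detected with the empty virus, a bound of at least 1.15-fold.

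Among genes lower with Nurr1, Apoe, the apolipoprotein made by astrocytes, was 7.46-fold lower, Abhd3 7.38-fold, the neuropeptide gene Npy 6.85-fold and Mfng, a glycosyltransferase that modifies Notch receptors, 6.44-fold. Kcne1l was 6.37-fold lower, Pdzph1 5.84-fold, the manganese transporter gene Slc30a10 5.81-fold and the GABA transporter gene Slc6a11 5.68-fold. Mfap4 was at least 7.05-fold lower, Bmp4 at least 6.70-fold, Rnase1 at least 4.07-fold and Alk at least 3.92-fold, since the Nurr1 array did not detect them.

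Genes of progenitor and glial cells were lower with Nurr1 as groups. Of 23 measured genes of neural progenitors and radial glia, 8 were at least 2-fold lower and none higher, with a list median of -0.73 (log2) below all 10000 random lists. Nr2e1 and Notch3 were each 2.52-fold lower, Sox3 2.44-fold and Aldoc 2.30-fold. The Notch list had a median of -0.96, with 5 of 12 genes lower, among them the Notch target genes Hes5 (2.18-fold) and Hey1 (2.11-fold). Of 16 astrocyte genes 7 were lower, such as the water channel gene Aqp4 (3.11-fold) and Atp1b2 (2.48-fold), while Ntsr2 (8.01-fold), Cd44 (3.20-fold) and Gja1 (2.15-fold) were higher, and the median was -0.97. The oligodendrocyte list had a median of -0.57, with Nkx2-2 3.23-fold and Cnp 2.46-fold lower and the tight junction gene Cldn11 3.92-fold higher. Wnt genes, a list that holds activators and antagonists together, had a median of -0.66. Among them Sfrp1 was 3.61-fold lower, and Rspo3, not detected with the empty virus, at least 3.75-fold higher. The medians of these 4 lists also lay below all random lists.

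Neuronal and cell cycle genes were higher with Nurr1. Of 30 pan-neuronal genes 8 were at least 2-fold higher, with a median of 0.39 above all random lists. The secretogranin gene Scg2 was 9.42-fold higher, the neurofilament gene Nefm 4.98-fold, the synaptotagmin gene Syt1 3.09-fold and Gap43, of growing axons, 2.86-fold. Rbfox3, which encodes the neuronal marker NeuN, was 2.80-fold lower and Cplx2 2.11-fold lower. All 26 measured cell cycle genes had values above Control, 13 of them at least 2-fold, with a median of 1.00. Nusap1 was 2.69-fold higher and Cenpa and Plk1 each 2.63-fold. Genes fed by growth factor signalling had a median of 0.85, with Dusp4 at least 11.9-fold, Ier3 6.63-fold, Ccnd1 4.34-fold and Dusp6 3.91-fold higher. Cortical glutamatergic genes had a median of 0.39 (percentile 99.8), with Nrn1 at least 6.87-fold and Bcl11b 2.70-fold higher and Neurod2 2.26-fold lower. The dopamine list had a median of 0.10, within the random range (percentile 93.7) though above it without a detection floor (0.50, percentile 99.9). Its members Ret, the receptor for glial cell line-derived neurotrophic factor, Gfra1, the co-receptor, and Ddc were at least 9.54-fold, at least 2.92-fold and at least 3.07-fold higher, and Nrip3 3.20-fold.

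With Foxa2 alone, some genes of the floor plate and of dopamine synthesis were higher and others were not. Ddc, encoding the enzyme that makes dopamine from L-DOPA, was at least 52.6-fold higher than Control, and Shh, the floor plate morphogen, at least 33.2-fold. Gch1, which starts the synthesis of the tyrosine hydroxylase cofactor, was at least 12.6-fold higher and Corin, a floor plate protease gene, at least 10.4-fold. Th had a signal of 237, a bound of at least 1.45-fold, and the dopamine transporter gene Slc6a3 was detected neither on this array nor on the Control array. At least 2-fold higher values were found for 279 genes and at least 2-fold lower values for 117.

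Ccn2 was 21.8-fold higher with Foxa2, Diras2 15.2-fold, the aspartyl protease gene Bace2 14.5-fold, Gpc3 12.6-fold and the ubiquitin ligase gene Neurl1a 12.3-fold. Dnajc12, a co-chaperone of aromatic amino acid hydroxylases, was also 12.3-fold higher, the endoplasmic reticulum oxidase gene Ero1b 11.6-fold and the TGF-beta receptor gene Tgfbr2 11.4-fold. Tmem255a was at least 14.8-fold higher and the smooth muscle actin gene Acta2 at least 13.5-fold. Dimmer probes, undetected on the Control array, gave smaller bounds (log2): 0.05 for Tgfbr2, 0.80 for Bace2, and 0.89 and 1.15 for Acta2. The second Gpc3 probe gave 4.35. Diras2 had a Control signal of 170, just above the lowest detected there (166). Apoe was 4.38-fold lower, Vgll2 4.03-fold, the neuronal connexin gene Gjd2 3.98-fold, Brinp3 3.92-fold and the tenascin gene Tnc 3.44-fold. Galnt13 was 3.43-fold lower, and Mfap4 and Bricd5 each 3.31-fold. Htra1 was at least 5.22-fold lower. Mc5r (at least 2.95-fold), Has2 (at least 2.67-fold) and Rsad2 (log2 -1.59, a bound) were also lower, but each fell short of 2-fold without background correction and with the authors' values.

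The list of midbrain and floor plate genes had a median of 0.25 with Foxa2 (percentile 98.7), with the axon guidance gene Slit2 8.05-fold higher and the proneural gene Neurog2 2.06-fold lower. Its position fell within the random range without background correction and with the authors' values (percentile 97.0 in both). Hedgehog response genes had a median of 0.23 (percentile 98.5). The Hedgehog target Hhip was at least 3.07-fold higher, Ccnd1 3.36-fold and the receptor gene Ptch1 2.04-fold, and Boc was at least 2.28-fold lower. Ccnd1 was also higher with Nurr1 alone, where the Hedgehog list had a median of -0.32 (percentile 2.03). That position was within the random range with detection at a p-value under 0.05 (percentile 3.53) and without a filter or floor (4.76). Genes of the BMP and TGF-beta response had a median of 0.61 above all random lists, with Tgfb2 4.13-fold, Tgfb3 at least 3.68-fold, Id3 2.62-fold and Id1 2.49-fold higher. Of 13 oligodendrocyte genes 4 were lower, Gpr17 by 2.96-fold, Cnp by 2.68-fold, Lims2 by 2.31-fold and Cspg4 by 2.09-fold, with a median of -0.91 below all random lists. Astrocyte genes (median -0.04, percentile 46.9) and progenitor genes (median -0.17, percentile 2.51) were within the random range, the latter so narrowly that 5 of 8 alternatives placed it below. Notch genes lay below the random range, though not with detection at a p-value under 0.05 (median -0.17, percentile 12.6). Genes of the dopamine list had a median of 0.00 (percentile 68.3), the value entered for members given no difference. Among its 14 measured members 6 lay above 0 and 4 below, and 17 of its 30 genes had a named probe.

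Cell cycle genes were higher with Foxa2 too, with all 26 above Control, 10 of them at least 2-fold, such as Uhrf1 (3.17-fold) and Mcm5 (2.64-fold), and a median of 0.82. Pan-neuronal genes had a median of 0.41 with 2 of 30 at least 2-fold higher, Scg2 (6.11-fold) and Cplx2 (2.56-fold). Growth factor feedback genes had a median of 0.41 that became 0.00 with detection at a p-value under 0.05. Foxa2 differed from Nurr1 in the balance of the counts, with 70.5% of its differing genes higher against 61.0%, a comparison that was not tested. Scaling to equal medians put 81.1% of the Foxa2 genes on the higher side, 365 against 85, and 70.4% of the Nurr1 genes, 429 against 180. For Foxa2, leaving out background correction lowered the count from 396 to 254.

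Nurr1 and Foxa2 shared part of their differences from Control. Among 7721 genes detected in both contrasts, 80 were at least 2-fold higher with each factor, where independent lists would share 10.1, and 57 were lower with each, against 3.35. Another 14 genes differed in opposite directions. The cell cycle inhibitor gene Cdkn1c was 4.54-fold lower with Nurr1 and 2.08-fold higher with Foxa2, and the Wnt antagonist gene Dkk3 2.63-fold lower and 2.81-fold higher. Both contrasts use the same Control array. The correlation of their log2 differences across 7127 genes was 0.413, against 0.499 in simulated unchanged arrays that share 1 control, and the covariance was 0.101 against 0.0176. The simulated correlation follows from equal noise and a shared control, whatever the size of the noise. No gene was 2-fold higher or lower in both contrasts of the simulated arrays. Their small noise made this foreseeable, as it came from the spread between probes and left out differences between cultures. How much of the overlap comes from the shared array cannot be separated with 1 Control array.

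With both factors, 4 genes of dopamine synthesis and transport were well above Control. Th was at least 44.1-fold higher, with a signal of 4470 against 101, Ddc at least 74.2-fold, Gch1 at least 20.9-fold and Slc6a3 at least 19.3-fold. The dopamine list had a median of 1.30, above all random lists, with 7 of 14 genes at least 2-fold higher. These also included Bdnf, encoding brain-derived neurotrophic factor (6.04-fold), Ret (at least 3.83-fold) and Nrip3 (3.17-fold), while the midbrain transcription factor gene En2 was at least 2.97-fold lower. Other genes of the tetrahydrobiopterin cofactor differed less, with Pts 1.52-fold lower and Qdpr 1.15-fold higher, and both were picked out after their values were seen. In all 566 genes were higher and 381 lower, the largest number of the 3 contrasts with Control. Scaling to equal medians divided the genes into 713 higher and 300 lower, or 70.4% higher in place of 59.8%.

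**Figure D1:**
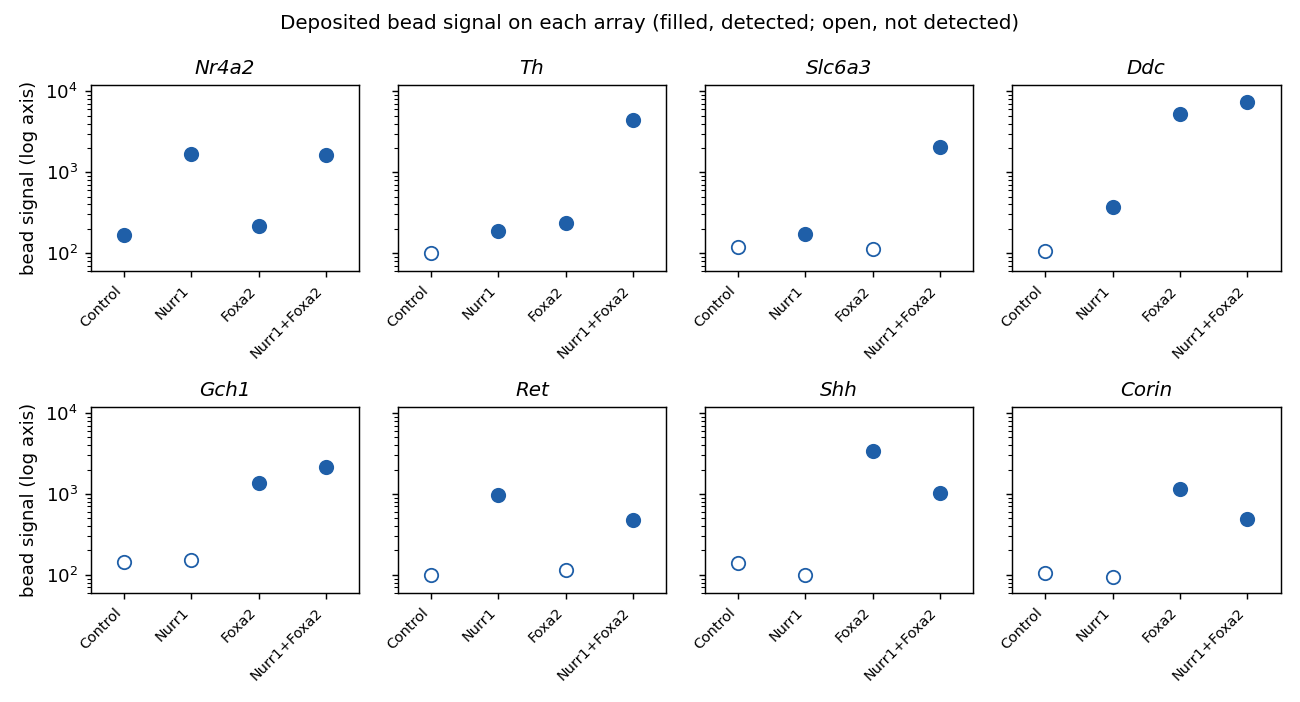
Deposited bead signal (log axis) of Nr4a2 and 7 genes of dopamine neurons or the floor plate on each of the 4 arrays, with filled points for detected and open points for undetected values. Th reached 4470 and Slc6a3 2023 with both factors, while Ddc was at 5243 and Shh at 3414 already with Foxa2 alone, and Ret was highest, at 969, with Nurr1 alone.

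Outside the dopamine genes, Lpl was at least 86.4-fold higher with both factors, Eno3 74.7-fold, Spon2 at least 47.4-fold, the mitochondrial protein gene Chchd10 44.4-fold and the carbonic anhydrase gene Car14 39.3-fold. The transcription factor gene Klf5 was 32.2-fold higher, Dnajc6, encoding the neuronal uncoating factor auxilin, 27.8-fold, Angpt2 23.4-fold, Minar2 22.2-fold and Aard 22.1-fold. Klf5 and Chchd10 had Control signals of 170 and 175, just above the lowest detected there (166). A second Angpt2 probe, undetected on the Control array, gave a bound of 1.62 (log2), and the second Dnajc6 probe gave 4.76. Apoe was 14.2-fold lower, Brinp3 11.5-fold, the adhesion molecule gene Vcam1 10.5-fold and Scrg1 by a log2 difference of -3.32. Kcne1l was 9.03-fold lower, Pdzph1 8.37-fold, Tmem100 8.34-fold and Gpr17, a receptor of oligodendrocyte precursors, 7.91-fold. Mfap4, Eepd1, Vgll2 and Aqp9 were at least 7.29-fold, 7.11-fold, 7.06-fold and 6.07-fold lower.

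Genes of oligodendrocytes were lower with both factors than on any other array. Of 13 genes 9 were at least 2-fold lower than Control, led by Gpr17, Nkx2-2 (6.36-fold), Cnp (6.06-fold) and Lims2 (5.44-fold), and Cldn11 was 2.61-fold higher. The list median was -1.59 against Control, -1.02 against Nurr1 and -1.18 against Foxa2, each below all random lists. Of 23 progenitor genes 14 were lower than Control, with a median of -1.09. Sox3 was at least 5.02-fold lower, Fabp7 4.69-fold, Hes5 4.28-fold and Aldoc 4.13-fold, and the RNA-binding protein gene Msi2 was 2.28-fold higher. Notch genes had a median of -1.15, with Nrarp 5.62-fold and Hey1 2.74-fold lower. Astrocyte genes had a median of -0.86, with 7 of 16 lower, Slc1a2 by 4.78-fold and Aqp4 by 3.48-fold, and Ntsr2 6.76-fold higher. The proneural gene Neurog2 was 7.76-fold lower and Cdkn1a, an inhibitor of the cell cycle, 6.76-fold higher. Cell cycle genes were nevertheless above Control in 25 of 26 cases, 7 of them at least 2-fold, with a median of 0.61. Pan-neuronal genes had a median of 0.17 (percentile 99.4), with Scg2 7.13-fold, Nefm 3.16-fold and the synaptophysin gene Syp 2.68-fold higher and Rbfox3 3.35-fold lower. Growth factor feedback genes had a median of 0.56, with 7 of 15 higher, such as Dusp4 (a bound of 3.47 in log2) and Dusp6 (4.10-fold).

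**Figure D2:**
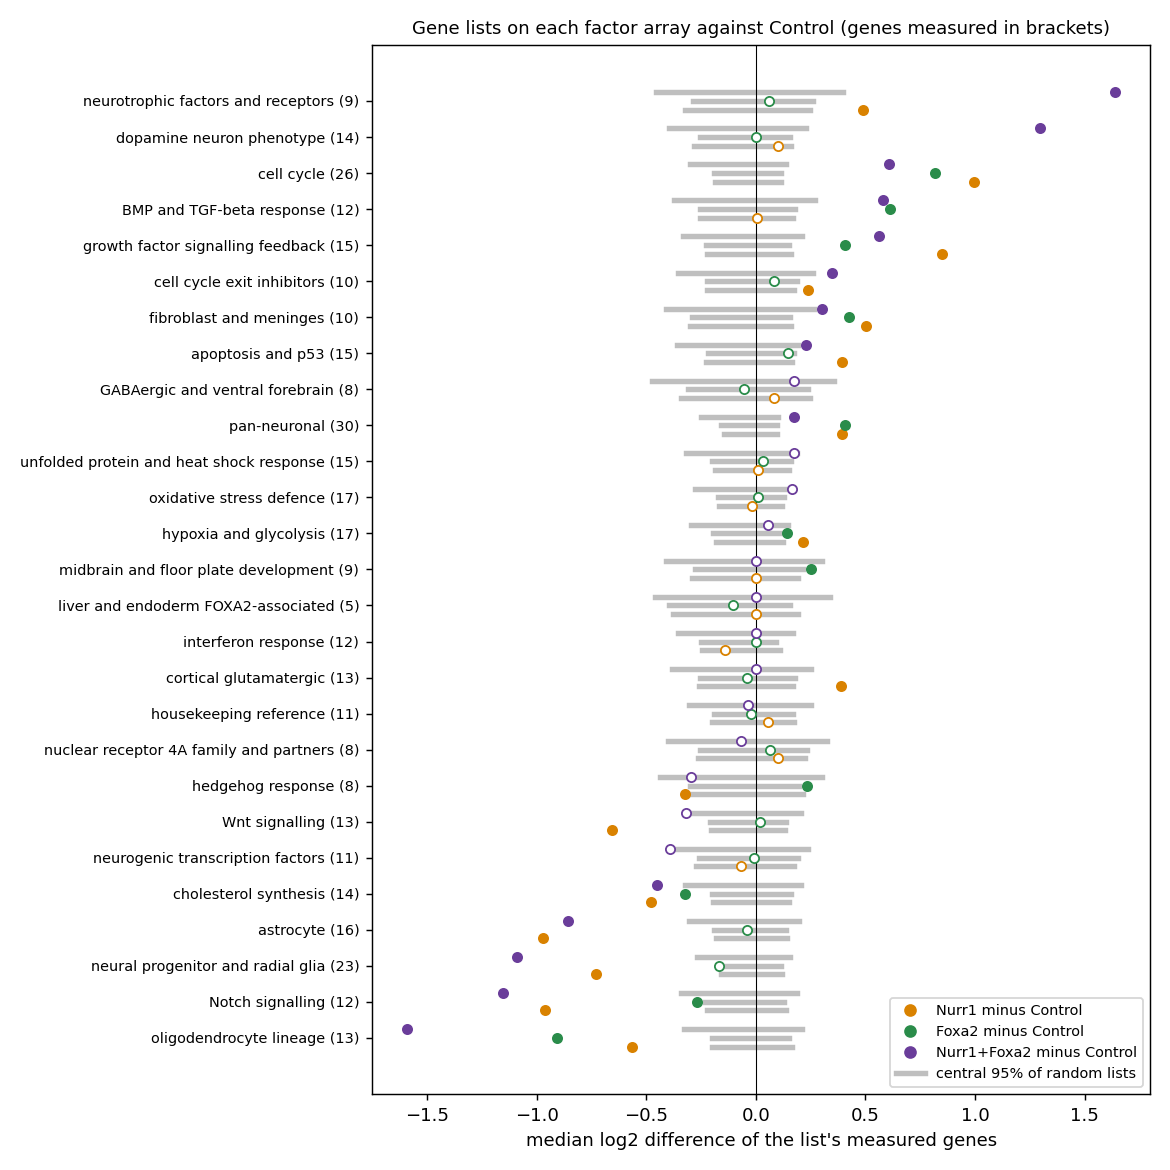
Median log2 difference from Control (horizontal axis) of the 27 gene lists with at least 5 measured genes, for each factor array, with the central 95% of 10000 signal-matched random lists as grey bars and filled points outside them. The oligodendrocyte list lay lowest with both factors (-1.59), and the cell cycle list was higher on all 3 arrays. The dopamine list stood at 1.30 with both factors, 0.10 with Nurr1 and 0.00 with Foxa2, the last a value entered for members given no difference.

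Against each single factor, the array with both factors shows what the second factor went with. Compared with Nurr1 alone, Th was 38.5-fold higher, Cldn10 27.2-fold, Palmd 26.1-fold, Ddc 24.2-fold and Mia 23.2-fold, and Slc6a3 was 20.5-fold higher from a signal just detected on the Nurr1 array (171). The pentraxin gene Nptx2 was 6.65-fold lower, Igfbp3 5.83-fold, Cytip 5.77-fold, Prkcq 5.65-fold and Chst8 5.44-fold. Genes numbered 352 higher and 138 lower (259 and 73 with the authors' values, which raised the share higher from 71.8% to 78.0%), and the dopamine list had a median of 0.26 (percentile 99.1). Lists below the random range included pan-neuronal genes (-0.26, percentile 0.33), cortical glutamatergic genes (-0.38, percentile 0.47) and progenitor genes (-0.34, percentile 0.08). Nr4a2 was 1.12-fold lower. Compared with Foxa2 alone, Eno3 was 74.7-fold higher, Lpl 51.5-fold, Th 30.4-fold, Cldn10 29.7-fold and Mia 23.6-fold, with Slc6a3 at least 22.7-fold higher. Prelp was 10.4-fold lower, Acta2 9.74-fold, Mfng 7.50-fold, Neurl1a 7.01-fold and Upp1 6.89-fold. Here 387 genes were higher and 310 lower, and the dopamine list had a median of 0.61 above 99.98% of random lists. Ddc (1.41-fold) and Gch1 (1.66-fold) were within 2-fold of Foxa2 alone.

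Floor plate and Hedgehog genes had lower values with both factors than with Foxa2 alone. Shh was 3.49-fold lower, Corin 2.68-fold, Hhip at least 3.56-fold and Ptch1 2.55-fold. The medians were -0.56 for midbrain and floor plate genes (percentile 0.04) and -0.91 for Hedgehog response genes, below all random lists. In these lists 4 of the 9 and 4 of the 8 genes were at least 2-fold lower and none was higher, with Nkx2-2 (4.30-fold) in both lists. Progenitor genes were also lower than with Foxa2 alone, 10 of 23 by at least 2-fold, with a median of -1.0, as were Notch genes (-0.94), astrocyte genes (-1.07) and Wnt genes (-0.56).

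Values with both factors were set against the sum of the single-factor differences. Of 7127 genes detected on all 4 arrays, 206 lay at least 2-fold above the sum and 218 at least 2-fold below, and the median departure was -0.03 (log2). Furthest above were the claudin gene Cldn10 (50.5-fold) and Mia (31.0-fold), each near or below the Control signal with either factor alone. They were followed by Il1rap (9.78-fold), the NF-kB regulator gene Nfkbiz (7.12-fold) and the retinol dehydrogenase gene Rdh5 (6.53-fold). Furthest below were Igfbp3 (21.3-fold), Ccn2 (15.2-fold), Gpc3 (14.6-fold), Neurl1a (10.7-fold) and Ecrg4 (8.50-fold). Of 61 genes at least 2-fold higher with each single factor, 46 lay below additivity and 1 above, and of 29 lower with each, 7 lay above and 0 below. Choosing genes by both single-factor differences favours these directions by construction, because the same values enter the departure. The between-probe SD of a departure was 0.24, over probes detected on all 4 arrays. Of genes with several such probes and a mean departure of at least 2-fold, 78 of 79 had the same sign in all of them. That spread made a shared sign foreseeable.

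Th and Slc6a3 were not detected on all 4 arrays and are outside those counts. With undetected values at the floor, the departure was 4.73 for Th and 4.36 for Slc6a3, and with the values left as measured 3.18 and 4.57. For Nr4a2 the departure was -0.48. The dopamine list had a median departure of 0.25 (percentile 95.3), within the random range. It lay above the range under 3 of 8 alternatives, with detection at a p-value under 0.05 (percentile 98.7), without a filter or floor (98.0) and with unmatched random lists (98.2). Ddc (-1.12), Ret (-1.32) and Gfra1 (-0.63) had departures below 0. Cell cycle genes lay below additivity, 14 of 26 by at least 2-fold, with a median of -1.11, as they were similarly high on all 3 factor arrays. Hedgehog genes (-0.53), pan-neuronal genes (-0.45) and oligodendrocyte genes (-0.41) also had medians below the random range. Pan-neuronal genes too had medians above Control on all 3 factor arrays (0.39 with Nurr1, 0.41 with Foxa2 and 0.17 with both). A Control array that stood apart would add to such a departure, and its share cannot be separated with 1 Control array. Progenitor genes had a median of -0.23 (percentile 2.07), which fell within the random range under 4 of 8 alternatives. These were no background correction (percentile 5.44), scaling to equal medians (79.0), the mean over probes (23.5) and the authors' values (5.01). With scaling to equal medians 163 genes lay above additivity and 261 below, or 38.4% above in place of 48.6%. On the linear scale, where signals rather than logarithms add, 318 lay above and 146 below.

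**Figure D3:**
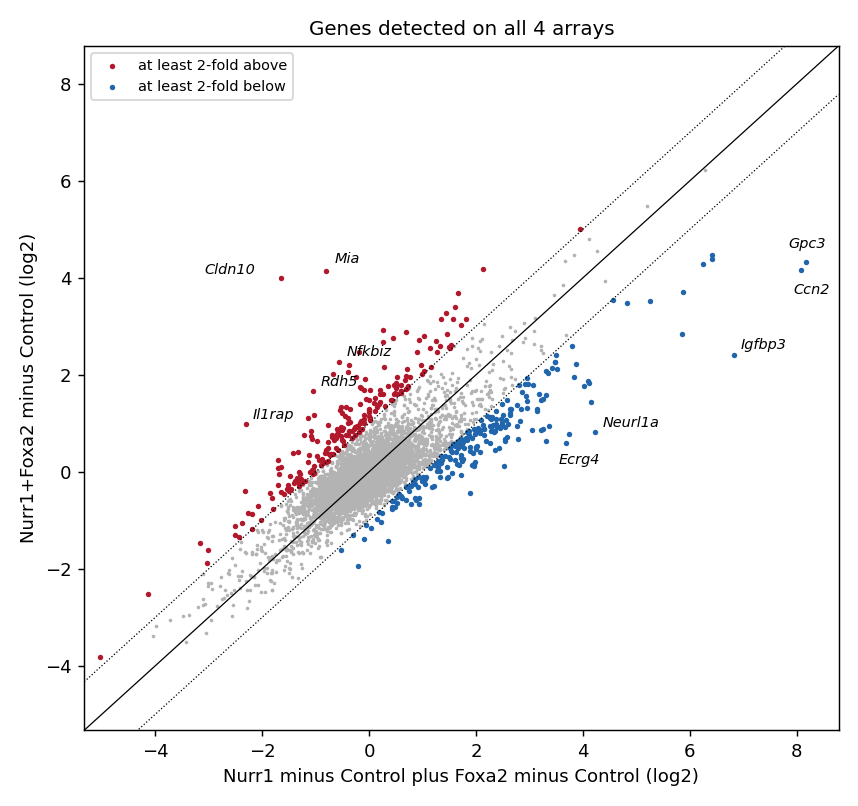
Log2 difference from Control with both factors (vertical axis) against the sum of the 2 single-factor differences (horizontal axis) for the 7127 genes detected on all 4 arrays, with additivity as a solid line and 2-fold departures as dotted lines. Cldn10 and Mia stand highest above the line and Igfbp3, Ccn2 and Gpc3 lowest below it, with 206 genes above and 218 below the dotted lines.

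Another 113 genes were detected only on the array with both factors. Of these 15 were at least 2-fold above the highest bound of the other arrays, and the leading 5 were the protease gene Ctsh (at least 23.4-fold), the growth factor gene Fgf10 (at least 16.3-fold), Cldn1 (at least 6.70-fold), Fkbp11 (at least 4.98-fold) and Kctd12b (at least 4.13-fold). These 5 fall outside the rule for named genes and were chosen after their values were seen.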

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

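Differences in this part were not tested, because each group had 1 array. Where an array did not detect a gene, the value is a bound from the floor. A total of 6 named genes differed at least 2-fold in opposite directions between Foxa2 and Control and between both factors and Nurr1. On the log2 scale, C1ql1 was -1.48 without Nurr1 and 1.46 with it, the latter a bound, and Il1rap was -1.25 without and 2.04 with it. The other 4 ran the opposite way: Cdh13 was 1.21 without Nurr1 and -1.22 with it, and Ecrg4 1.97 and -1.12. Igfbp3 was 1.87 without and -2.54 with it, and Melk, a cell cycle kinase gene, 1.00 (a bound) and -1.11.

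For the Nurr1 difference there were 8 such genes. C1ql1 was -1.48 (a bound) without Foxa2 and 1.45 with it, and Il1rap -1.07 and 2.22. Acta2 was 1.16 (a bound) without Foxa2 and -3.28 with it, Arhgap24 1.24 (a bound) and -1.27, Ecrg4 1.72 and -1.37, and the glutamate receptor gene Gria1 1.06 and -1.9. Melk was 1.09 (a bound) without and -1.02 with it, and the retinoic acid receptor gene Rarb 1.56 (a bound) and -1.43. The other 2 Acta2 probes were detected on neither the Control nor the Nurr1 array and did not show the difference without Foxa2. C1ql1, Ecrg4, Il1rap and Melk stood in both groups of genes, and all comparisons with the Control array share its error.

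Probes outside the authors' value table, which have no gene name here, also held signal above Control. Of these 12451 probes, 13 were at least 2-fold higher with Nurr1, 20 with Foxa2 and 43 with both factors. The highest of them was ILMN_2965903, with a signal of 11659 on the array with both factors against 130 on the Control array. Next came ILMN_1247347, at 8700 against 78.5. Neither was detected on the other 3 arrays.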

How the results depend on the processing

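All alternatives in this part were planned before the data were examined. Of 51 total counts recomputed, 48 stayed within 1.5 times the reported total. The exceptions were the 396 genes of Foxa2 against Control, which became 254 without background correction and 257 with the authors' values, and the 424 departures from additivity, which became 712 without a detection filter or floor. Leaving out background correction shrinks differences of dim genes, and leaving out the filter adds genes that were not detected on all 4 arrays. The separate counts of lower genes moved further without background correction and with the authors' values. They went from 117 to 55 and 57 for Foxa2 against Control, from 138 to 77 and 73 for both factors against Nurr1, from 310 to 201 and 199 for both against Foxa2, and from 221 to 146 in each setting for Nurr1 against Control. Genes above additivity went from 206 to 137 without background correction, and to 318 on the linear scale. Over all settings the total counts ranged from 389 to 730 for Nurr1 and from 715 to 1150 for both factors against Control. Scaling to equal medians moved the median difference of all genes by 0.08 to 0.10 for the contrasts with Control. Of 162 list positions 75 lay outside the random range, and 66 to 79 did under the alternatives. The BMP and TGF-beta list turned, with a median of 0.58 for both factors against Control that became -0.19 with detection at a p-value under 0.05, and the cause was not tested. Of 105 named differences past 2-fold, each kept its direction in the settings that gave it a value, and 102 stayed past 2-fold without background correction and with the authors' values. Their sizes did depend on the background. All 105 were smaller without background correction and 104 with the authors' values, with a median ratio of 0.848 on the log2 scale in each. By more than the spread between probes, 92 of 110 named differences moved in each of these settings and 67 with an offset of 50. The low signal of genes such as Th on the Control array (101, undetected) limits folds against it to bounds.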

Other observations

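Among members of the oxidative stress list past 2-fold, the metallothionein genes, whose proteins bind zinc and copper, were grouped after their values were seen, and the group was not tested. With both factors, Mt2 was 7.32-fold above Control, Mt3 4.61-fold and Mt1 2.26-fold, against 1.58-fold, 1.87-fold and 1.18-fold with Nurr1 and 1.03-fold, 1.05-fold and 1.03-fold with Foxa2. Of that list 4 of 17 members were higher than Control with both factors. The list median there was 0.16, within the random range (percentile 96.9), though above it without background correction and with the authors' values (percentiles 97.7 and 97.8). Its median departure from additivity was 0.26 (percentile 99.3), while the glutathione transferase gene Gstm1 was 4.47-fold lower than Control. Vegfa, the vascular growth factor gene, was 7.56-fold above Control with both factors, 1.40-fold with Nurr1 and 1.17-fold below with Foxa2. With Bdnf and Ret it belongs to the neurotrophic list, whose median was 1.64 with both factors (percentile 99.99), 0.49 with Nurr1 (percentile 99.8) and 0.06 with Foxa2 (percentile 77.4). In the same list the neurotrophin receptor genes Ntrk2 and Ntrk3 were 3.19-fold and 2.69-fold lower than Control with both factors. The early B-cell factor genes Ebf1 (at least 2.56-fold) and Ebf3 (2.05-fold) were higher with both factors, in a list of neurogenic transcription factors with a median of -0.39 (percentile 2.68). That position was within the random range, but 5 of 8 alternatives placed it below, at percentiles from 1.43 to 2.39.

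Cholesterol synthesis genes had medians of -0.48 with Nurr1, -0.32 with Foxa2 and -0.45 with both factors, all below the random range, though no member differed 2-fold. Apoptosis and p53 genes had medians of 0.39, 0.15 and 0.23, with Cdkn1a 6.76-fold and Fas 3.08-fold above Control with both factors. Averaging over probes put the values with Nurr1 and with both factors within the random range (percentiles 96.8 and 95.3). The value with both factors was also within it without background correction (94.5), with an offset of 50 (96.5) and with the authors' values (95.3). Inhibitors of the cell cycle had medians of 0.24, 0.08 and 0.35, likewise within the range when probes were averaged (percentiles 95.2 and 94.0 for Nurr1 and both). Fibroblast and meninges genes had medians of 0.50, 0.42 and 0.30, with Igf2 4.81-fold higher with Nurr1, and the value with both factors fell within the range under 4 alternatives. Hypoxia and glycolysis genes had medians of 0.22, 0.14 and 0.06. The value with Foxa2 lay above the random range but fell within it under several alternatives. Their percentiles ran from 91.7 (mean over probes) to 97.0 (detection at a p-value under 0.05). The medians with Nurr1, Foxa2 and both were 0.08, -0.05 and 0.17 for GABAergic genes, -0.14, 0.00 and 0.00 for interferon genes, and 0.01, 0.03 and 0.17 for unfolded protein and heat shock genes. For liver and endoderm genes they were 0.00, -0.10 and 0.00, for the nuclear receptor 4A family 0.10, 0.06 and -0.07, and for housekeeping genes 0.05, -0.02 and -0.04, all within the random range, except that interferon genes with both factors lay above it with detection at a p-value under 0.05 (percentile 97.9). Only 5 of the 44 liver and endoderm genes were measured, and 7 had a named probe. Their medians of 0.00 are entries for genes given no difference, so they show little about that group. Of the 6 lists too short to be placed, microglia, endothelial and neural crest genes had 2 measured members each, inflammatory genes 3, choroid plexus genes 4 and other monoaminergic and cholinergic genes 0. Their medians with both factors were -0.14, -0.80, 0.29, -0.99 and 0.00 in that order, with none for the last.

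Tests of 3 patterns follow. Those of general glial loss, of the Control array standing apart and all 3 on Th and Slc6a3 were chosen after the results were seen. The first pattern is the low oligodendrocyte list with both factors. Scaling or background handling is argued against, since the list median stayed at or below -1.415 under 4 other settings. A general loss of glial and progenitor RNA stays open, since the astrocyte median was 0.732 above the oligodendrocyte median on that array, less than the spread of the members (SD 1.24 and 1.58), and the progenitor and Notch lists were low there too. Fewer cells of the lineage, or lower expression per cell, may each underlie it and cannot be told apart here, as 1 of 13 members, Cldn11, was higher with both factors, and 3 members (Olig2, Nkx2-2 and Cspg4) are also in other lists.

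The second pattern is the higher cell cycle list on all 3 factor arrays. Scaling or background handling is argued against, since its lowest median was 0.476 over 4 other settings and 3 arrays. A Control culture with unusually few dividing cells could give the same values as an action common to both factors. The largest list median between any pair of factor arrays was -0.216, and with 1 Control array these cannot be told apart.

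The last pattern is the departure of Th and Slc6a3 from additivity. A higher Nr4a2 level with both factors is argued against at the Nr4a2 probe, which was -0.158 (log2) relative to Nurr1 alone. Whether that probe reads the transcript carried by the virus is not known. A difference in the Nurr1 delivered by the virus therefore cannot be excluded. Processing is argued against because the lowest departure of either gene was 3.181 over 7 other settings. A general excess of signal as large as these departures is argued against by the deposited signals before any normalization. There the median departure was -0.108 over 7127 genes (SD 0.45) against 3.34 for Th and 3.61 for Slc6a3. The similar median signals of the arrays made this outcome foreseeable, so it adds little. A joint action of both factors on these genes remains a hypothesis that may account for the values, as would a difference in Foxa2 level or in the culture behind the array, which were not tested.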
